A study of Setaria viridis with 18 samples.

How the data were processed

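Small RNAs of Setaria viridis were measured by sequencing 18 libraries in 9 groups of 2. The labels name leaf, whole panicle stages 1 to 5 and spikelet stages 2 to 4, and the series description calls the 2 libraries of each group biological replicates. Nothing states from which plants or plots they came, so each p-value measures the spread between these samples. According to the protocol in the labels, libraries were built after Lu and co-workers and an Illumina TruSeq preparation, run on an Illumina HiSeq instrument, freed of adapters and tallied per distinct sequence. Each deposited file therefore holds, per the labels, a read count for each distinct small RNA sequence of 1 library. Values were whole numbers for sequences of 18 to 34 nt, with no scaling by the authors visible in them. No alignment or genome build is given in the sources used here.

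Reads of 18 to 30 nt were used and their sum was the library size. That sum ran from 13682482 to 31898944 reads, so that 3 counts in a library stood for 0.0940 to 0.219 counts-per-million (CPM). Reads of 31 to 34 nt were tallied and left out. Tags, meaning distinct sequences, of 20 to 24 nt with at least 4 reads in at least 2 libraries were kept, 731590 in number, 67661 of 21 nt and 519165 of 24 nt. A ratio against a group at 0 was computed against a floor of 3 counts over the pooled reads of that group and is written as a lower bound. Groups with 1 to 3 counts have the ratio of pooled CPM with its exact 95% interval. Intervals and floors cover counting error only, because reads copied by PCR are not independent molecules.

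Tags of 20 to 22 nt were assigned to 29 conserved miRNA families when their first 18 nt matched a mature sequence with at most 1 mismatch. The mature sequences, a plant 5.8S rRNA sequence and the 22-nt oligo of the small RNA kit, GAATTCCACCACGTTCCCGTGG, were written from general knowledge and checked against no database. The families formed 9 lists, named phase change and inflorescence, phasiRNA triggers, TAS3 product, auxin response, meristem and organ patterning, anther and GAMYB, nutrient and copper response, silencing machinery, and other conserved. Abbreviations for groups such as miR156 are family names and do not separate loci.

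No genome was used, so loci of phased small RNAs (phasiRNAs), their share of reads and their base composition were not determined. In their place, as laid down for that event, single tags of 21 nt (27510 tested) and of 24 nt (135483 tested) were compared without knowing where they come from. A tag of either length can be a phasiRNA, a miRNA, a heterochromatic small interfering RNA or a fragment of another RNA, and a tag carried by 1 library can also come from another organism or another library.

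Families and tags were tested with the edgeR quasi-likelihood test (edgeR 4.0.16 under R 4.3.3). All 18 libraries were in 1 fit with group as the only term, the low-count filter of edgeR, total 18 to 30 nt reads as library size and no TMM factor. The 8 contrasts were the mean of the 8 panicle and spikelet groups against leaf, each whole panicle stage against the stage before, spikelet stage 3 against 2 and 4 against 3, and spikelet against whole panicle averaged over stages 2, 3 and 4. A further 2 interaction terms compared the stage change in spikelet with that in whole panicle. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and 0.05 was the threshold. For each list, the number passing when p-values were adjusted over the list alone is given as well. Shares of reads by length were compared with two-sided exact permutation tests, adjusted over 15 tests of 5 lengths in 3 comparisons, and spikelet was permuted against whole panicle within stage. A pair of groups of 2 libraries each was not tested for its shares, since so few libraries cannot give a small p-value.

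Families named for a contrast were those past the threshold with the 10 largest log2 changes in either direction. The phasiRNA triggers miR2118, miR2275 and miR390 and the TAS3 product tasiR-ARF were named in every contrast. Any other family is said to have been named after its values were seen. These choices, the tests, the lists and most alternatives were set before the data were examined.

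Alternatives for the counts were DESeq2 1.42.0 with its own size factors, TMM factors, library size from miRNA reads, other limits on mismatches, another low-count filter, fits of the compared groups alone, a replicate term and each library left out in turn. Library size without the kit oligo, library size from 20 to 24 nt reads without it, leaving out the stage 2 groups and, for tags, DESeq2 and leaving out single libraries were added after the data had been seen. The lone library of a group whose other library was left out was assumed to vary like the other groups. The low-count filter was applied anew in each of these fits. Counts of called tags without a library therefore also reflect which tags were tested and how their spread was estimated.

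The fits were tested on simulated data, with a fixed spread between replicates for each set of features that was the same in all groups. The measured spread differed between groups, so the rates below need not hold for the measured data. For families at whole panicle stage 3 against 2, 3 of 3 simulated 8-fold changes, 1 of 1 4-fold change and 2 of 5 2-fold changes were recovered. For single tags, 6.35% of the 8-fold changes were recovered at 21 nt and 24.2% at 24 nt in that contrast, and 40.9% and 70.3% in panicle against leaf. In panicle against leaf 17.0% of the simulated 24-nt calls and 3.45% of the 21-nt calls were false, with few changed tags simulated. The false 24-nt calls were 8 tags, 0.00812% of the unchanged ones, and the share does not carry over to the measured calls. A low count of called tags between adjacent stages is therefore a weak measure of absence of change. A called tag is described as carried by 1 library when that library was at least 10-fold above its replicate. Calls were made on the same libraries, so called families or tags whose groups lie apart give no separate support for a change.

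Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, version 1.17.8 of data.table and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.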

Results

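Small RNAs of green foxtail, Setaria viridis, a panicoid grass, were sequenced from leaf, from whole panicles at 5 stages and from spikelets at 3 of these stages, with 2 libraries in each of 9 groups. Whole panicles of stage 1 measured 1.5 cm and, like those of stage 2, were still enclosed by the leaf sheath. Those of stage 3 were emerging, those of stage 4 had fully emerged, and those of stage 5 had also been pollinated. The series description names only 1 group of enclosed whole panicles, and the labels, which were followed, give 2. Spikelets were taken at stages 2, 3 and 4. The series was made to test a sequence classifier on phasiRNAs, phased 21- and 24-nt small RNAs that are made from long precursors and are abundant in grass anthers. Libraries held between 14020824 reads (spikelet stage 2, replicate 2) and 32995658 reads (whole panicle stage 3, replicate 1). Levels are given in CPM, counts-per-million of the 18 to 30 nt reads, and n is 2 libraries per group unless stated.

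The division of reads by length addresses whether tissues and stages differ in the classes that Dicer enzymes make. In panicle and spikelet, 24-nt reads, the length typical of heterochromatic small interfering RNAs and of the later class of phasiRNAs, took 27.4% ± 4.72 of reads (SD, n = 16) against 16.8% ± 0.64 in leaf (n = 2). Whole panicles had 25.9% ± 2.51 of reads at 24 nt at stage 1 and 33.6% ± 1.36 at stage 4, and spikelets had 24.8% ± 2.76 at stage 2 and 20.9% ± 0.10 at stage 4. The share of 21-nt reads, the length of most miRNAs and of the earlier class of phasiRNAs, was 22.7% ± 4.01 in panicle and spikelet and 25.2% ± 0.90 in leaf. At 22 nt the shares were 14.8% ± 5.35 in panicle and spikelet and 25.9% ± 1.82 in leaf, and the kit oligo alone made up 19.2% ± 1.86 of all leaf reads and 17.7% ± 15.8 in spikelet stage 2, against 4.61% to 10.6% in the other groups. The oligo also enters the total of every share. With it removed, 24-nt reads were 20.8% ± 0.31 in leaf, 31.1% ± 9.34 in spikelet stage 2 and 23.2% ± 0.52 in spikelet stage 4. At 21 nt leaf then had 31.2% ± 1.83, and the panicle and spikelet groups 18.8% to 31.8%. Within the same stages, spikelet had 22.9% ± 2.15 of reads at 24 nt (n = 6) and whole panicle 31.4% ± 2.10 (n = 6). Whole panicle stages 3 to 5 and stages 1 and 2 had 31.8% ± 3.06 (n = 6) and 27.7% ± 2.78 (n = 4).

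None of the 15 exact permutation tests of these shares passed after adjustment, all being two-sided. The comparisons with leaf and between whole panicle stages shuffled single libraries. They thus treated replicates of a group as independent of each other, and the 16 panicle and spikelet libraries come from 8 groups. The 24-nt share differed by 10.6 percentage points between panicle and leaf (exact p = 0.0131, adjusted p = 0.0926) and by -8.59 between spikelet and whole panicle (exact p = 0.00926, adjusted p = 0.0926), each p being the smallest that its 153 or 216 permutations can give. At 22 nt panicle differed from leaf by -11.1 points (exact p = 0.0392, adjusted p = 0.118) and spikelet from whole panicle by 4.83 (exact p = 0.0185, adjusted p = 0.0926). The change from stages 1 and 2 to stages 3 to 5 was 4.10 points at 24 nt (exact p = 0.0762, adjusted p = 0.163) and 4.30 at 21 nt (exact p = 0.133, adjusted p = 0.222). Without spikelet stage 2 replicate 2 the 24-nt differences were 10.6 and -9.37. That setting was adjusted over fewer tests than 15, because the comparison of whole panicle stages does not hold this library. Its passing the threshold is therefore not comparable with the values above. With the kit oligo removed the 22-nt difference of spikelet from whole panicle turned to -0.0725, and counted over distinct sequences the 24-nt difference of panicle from leaf turned to -0.0029.

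**Figure D1:**
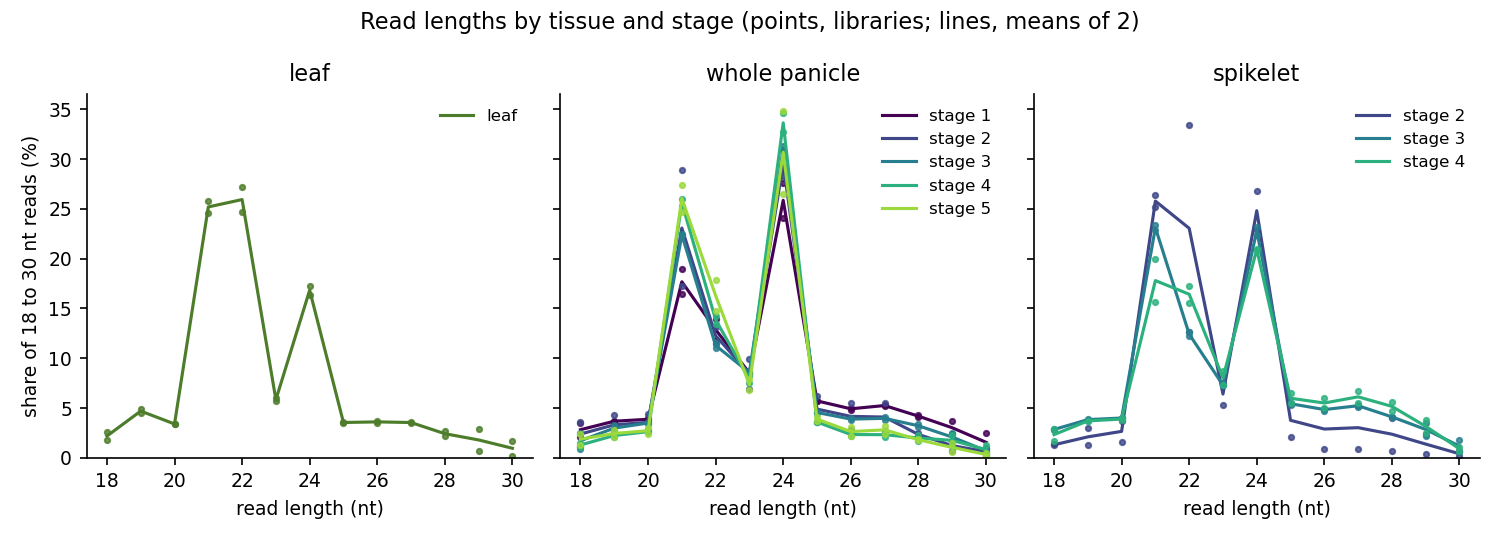
Share of reads (percent of 18 to 30 nt reads, y axis) by read length (nt, x axis) in the 9 groups, in a panel per tissue, with points for the 2 libraries and lines through group means. The 24-nt share ran from 16.8% in leaf to 33.6% in whole panicle stage 4, and the 22-nt share of leaf includes the kit oligo at 19.2% of reads.

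Signs of RNA quality and the similarity of replicates differed between groups. Fragments of 5.8S rRNA made up 0.445% ± 0.047 of leaf reads, between 0.437% and 0.908% in whole panicle, and 0.443% ± 0.460, 0.905% and 1.12% ± 0.21 in spikelet stages 2, 3 and 4. Reads shorter than 20 nt were 6.89% in leaf, 6.50%, 5.71%, 4.70%, 3.53% and 4.32% at whole panicle stages 1 to 5, and 3.41%, 6.68% and 6.04% at spikelet stages 2, 3 and 4. Reads assigned to the 29 miRNA families made up 18.9% ± 0.90 in leaf, 12.4% in whole panicle stage 1, 15.8% ± 7.38 in stage 2 and 11.4% ± 2.97 in spikelet stage 4. Replicates of spikelet stage 2 and of whole panicle stage 2 correlated across 21-nt tags, which are not independent replicates, with r of 0.659 and 0.809, against 0.889 to 0.968 in the other groups. Whole panicle stage 2 replicate 1 lay closest to a stage 3 library (r = 0.935) and replicate 2 to a stage 1 library (r = 0.879). The most abundant sequence assigned to a family was TCGGACCAGGCTTCATTCCCC of miR166, a regulator of leaf polarity genes named after its values were seen, with a mean of 102233 CPM over the groups.

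Panicle and spikelet together were compared with leaf to separate reproductive from vegetative small RNAs. The phasiRNA trigger miR2118, which starts the 21-nt phasiRNA pathway of grass anthers, rose from 0.217 to 9.28 CPM, a log2 change of 5.25 (SE 0.62, n = 16 and 2, adjusted p = 7.8e-08). The trigger of 24-nt phasiRNAs, miR2275, had 865 reads in panicle and spikelet and 0 in 37045134 leaf reads, and was at least 27.2-fold higher. All of these reads differed by 1 mismatch from the sequence used, and with exact matches miR2275 had 0 reads in every library. The largest measured rises were those of miR319, a regulator of TCP genes in organ growth, by 6.30 (SE 0.44, 1738 against 21.8 CPM), and of miR529, a regulator of SPL genes in inflorescences, by 5.79 (SE 0.50, 629 against 10.3 CPM). The TAS3 product tasiR-ARF, a repressor of auxin response factor genes, rose by 1.69 (SE 0.41, 4.93 against 1.22 CPM, adjusted p = 7.9e-04), and miR390, which starts its production, had 31.2 CPM in panicle and spikelet and 18 in leaf (log2 change 0.48, SE 0.30, adjusted p = 0.15). For miR2118, miR319 and miR529 every panicle and spikelet library lay above both leaf libraries.

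Leaf was richer in the other SPL regulators and in regulators of auxin response. In panicle and spikelet miR156, the juvenile-phase repressor of SPL genes, fell by 3.43 on the log2 scale (SE 0.24, 54.0 against 477 CPM), and its relative miR535 fell by 3.07 (SE 0.22). Levels of miR167, which acts on auxin response factor genes, fell by 4.11 (SE 0.25, 541 against 6343 CPM, adjusted p = 4.2e-12), and those of miR393, which acts on auxin receptor genes, by 3.49 (SE 0.26, 7.92 against 66.7 CPM). The regulator of ARGONAUTE mRNA, miR168, fell by 3.12 (SE 0.20, 1393 against 10907 CPM), and miR169, which acts on NF-Y subunit genes, fell by 4.18 (SE 0.34, 0.695 against 9.96 CPM). For these 6 families every panicle and spikelet library lay below both leaf libraries.

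By list, phase change and inflorescence had 1 family up and 4 down of 5, phasiRNA triggers 2 up of 3, TAS3 product 1 up of 1, and auxin response 3 down of 3. Meristem and organ patterning had 1 up and 2 down of 5, nutrient and copper response 5 down of 7, silencing machinery 2 down of 2, other conserved 1 down of 2, and anther and GAMYB 0 of 1. The numbers past the threshold were the same in each list when adjusted over the list alone. In total 5 families rose and 17 fell of 29. With DESeq2 size factors, which moved the median log2 change of the families from -1.22 to 0.24, 11 rose and 9 fell, and miR528, miR399 and miR164, named after their values were seen, changed sign to 0.25, 0.48 and 0.24, while miR390 passed at 1.97. The other scalings gave medians from -1.72 (TMM factors, where miR390 turned to -0.01) to -0.85, and with exact matches tasiR-ARF had 0.60 and no longer passed.

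**Figure D2:**
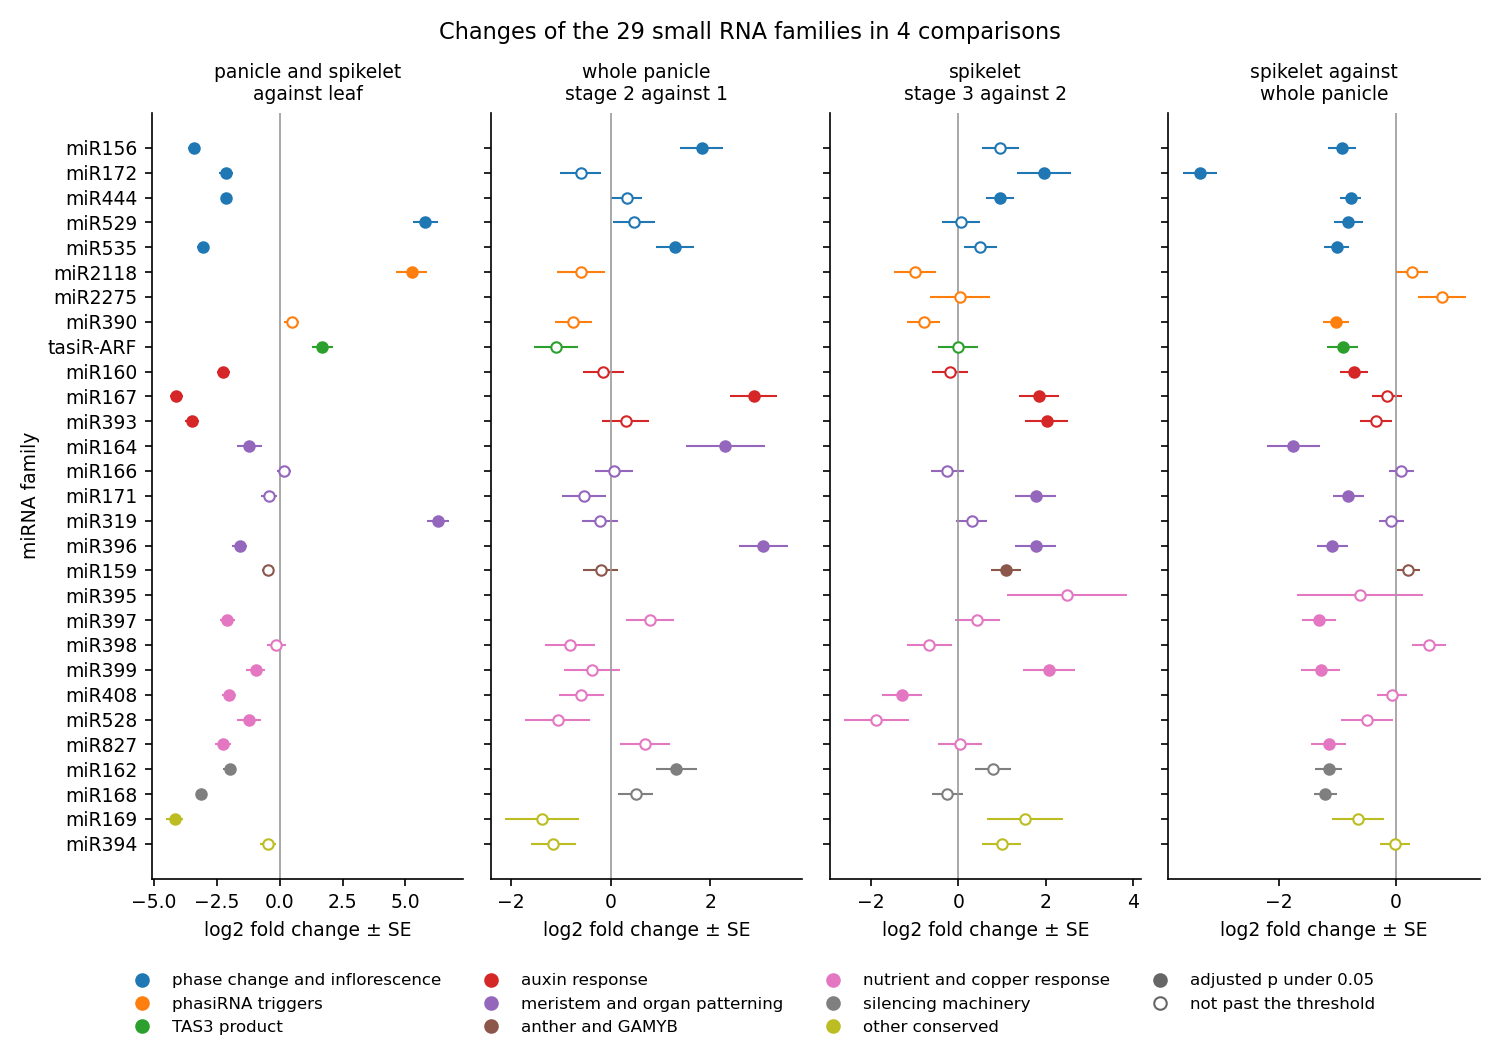
Log2 fold change with SE (x axis) of each miRNA family (y axis, coloured by list) in 4 comparisons, filled where the adjusted p was under 0.05; families with 3 counts or fewer in a compared group are not drawn. In panicle and spikelet against leaf, miR319 at 6.30 and miR529 at 5.79 stand highest and miR169 at -4.18 lowest, and 17 of 29 families fell, 3 of which (miR528, miR399, miR164) are positive with DESeq2.

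Single tags also differed between panicle and leaf. Of the tested 21-nt tags 9605 rose in panicle and spikelet and 3421 fell, and of the 24-nt tags 18277 rose and 8202 fell. The risen 21-nt tags summed to 38362 CPM in panicle and spikelet and 3076 in leaf, and the risen 24-nt tags to 41288 and 2123 CPM. Among risen 24-nt tags 33.5% started with C and 37.9% with A, and among fallen ones 3.96% and 72.3%. Of the risen 21-nt tags 98 belonged to the 29 families. Without leaf replicate 1 the called tags numbered 7626 (21 nt) and 11073 (24 nt), and without leaf replicate 2 they numbered 8526 and 11834. The median log2 change over all tags was 3.48 at 21 nt and 1.12 at 24 nt, and over the other scalings it ran from 2.46 to 3.33 and from 0.77 to 0.96. TMM factors gave 11808 up and 14706 down at 24 nt, library size without the oligo 15005 and 10855, and that from 20 to 24 nt reads 15118 and 11906.

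From stage 1 to stage 2 of the whole panicle, while the panicle was enclosed, 7 of 29 families rose and 0 fell. The growth-regulating factor repressor miR396 rose by 3.07 on the log2 scale (SE 0.49, 32221 against 3829 CPM, adjusted p = 7.7e-05) and miR167 by 2.87 (SE 0.48, 283 against 38.7 CPM, adjusted p = 7.7e-05). The trigger of 24-nt phasiRNAs, miR2275, went from 3 to 47 reads, a ratio of 12.5 (exact 95% interval 4.02 to 62.7), and passed with an adjusted p of 0.0205. Of the 47 reads 42 were in stage 2 replicate 1, the log2 change of 3.66 was 1.16 without that library and 7.50 without stage 1 replicate 2, and none of the reads was an exact match. The SPL regulators miR156 and miR535 rose by 1.83 (SE 0.43, adjusted p = 0.00364) and 1.30 (SE 0.38, adjusted p = 0.0190), miR164, a regulator of NAC boundary genes, by 2.31 (SE 0.79, adjusted p = 0.0327, from 6 and 1 reads at stage 1), and miR162, which acts on Dicer mRNA, by 1.32 (SE 0.41, adjusted p = 0.0205). In all 7 both stage 2 libraries lay above both stage 1 libraries. The change of miR164 was 3.94 and 1.60 without stage 1 replicates 1 and 2, not past the threshold in the latter case or with DESeq2 or TMM factors. The other named families did not pass: miR2118 had a log2 change of -0.60 (7.50 against 11.3 CPM), miR390 -0.75 (SE 0.38, adjusted p = 0.176) and tasiR-ARF -1.10 (SE 0.44, adjusted p = 0.0717), the last with a p of 0.0223 when adjusted over the list alone and past the threshold with TMM factors (-1.42) and DESeq2 (-1.35), but turned to 0.88 with exact matches, where it did not pass.

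By list this stage change held 2 risen of 5 in phase change and inflorescence, 1 of 3 in phasiRNA triggers, 1 of 3 in auxin response, 2 of 5 in meristem and organ patterning, 1 of 2 in silencing machinery and 0 in the rest, with none fallen. The numbers were the same when adjusted over the list alone, except that the TAS3 product (1 of 1) and other conserved (1 of 2, miR394 at -1.15, named after its values were seen) then passed, both lower. Stage 2 replicate 1 decided much of this: without it 2 families passed, miR167 rose by 1.47 and miR156 had 0.77, and without stage 1 replicate 2 the number was 3. The median change of families was 0.07, and from -0.29 to 0.07 over the other scalings, with 5 up and 3 down under TMM factors, 6 and 2 under DESeq2, 6 and 4 with library size from miRNA reads and 7 and 2 with that from 20 to 24 nt reads.

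Among 21-nt tags 7916 rose from stage 1 to stage 2 and 29 fell. Leaving out members of the miRNA families, the risen set summed to 1644 ± 571 CPM at stage 1, 20901 ± 16995 at stage 2, 38180 ± 2609 at stage 3, 39748 ± 13722 at stage 4 and 25190 ± 4144 at stage 5. In spikelet it summed to 53331 ± 24450, 22265 and 11364 CPM at stages 2, 3 and 4, and in leaf to 24647 CPM, of which 22462 ± 164 were a single sequence, TTCGGACCAGGCTTCATTCCC, a shifted form of miR166 named after its values were seen. The set's first base was C in 39.4% of tags, against 28.9% of the tags not called. For 20.1% of the risen tags another risen tag was complementary to it with the 2-nt 3' overhang that Dicer enzymes leave, against 0.884% and 0.985% at overhangs of 1 and 3 nt. Both stage 2 libraries exceeded both stage 1 libraries for 7705 of the 7916 tags, and 703 tags were carried by 1 library, 697 of them by stage 2 replicate 1.

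The number of called 21-nt tags was 7945 in both directions, 4169 without stage 1 replicate 1, 727 without stage 1 replicate 2 and 1630 without stage 2 replicate 1. The median change over 21-nt tags was 1.23 and from 0.91 to 1.16 over the other scalings. At 24 nt 570 tags rose and 8 fell, but 260 of the risen were carried by 1 library, each time stage 2 replicate 1. The 24-nt count of 578 was 10 with TMM factors, 13 with library size from 20 to 24 nt reads, 2341 with DESeq2, 127 without stage 2 replicate 1, 6446 without stage 2 replicate 2 and 1297 and 1143 without stage 1 replicates 1 and 2. The median over 24-nt tags was 0.31 and from 0.02 to 0.30 over the other scalings.

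**Figure D3:**
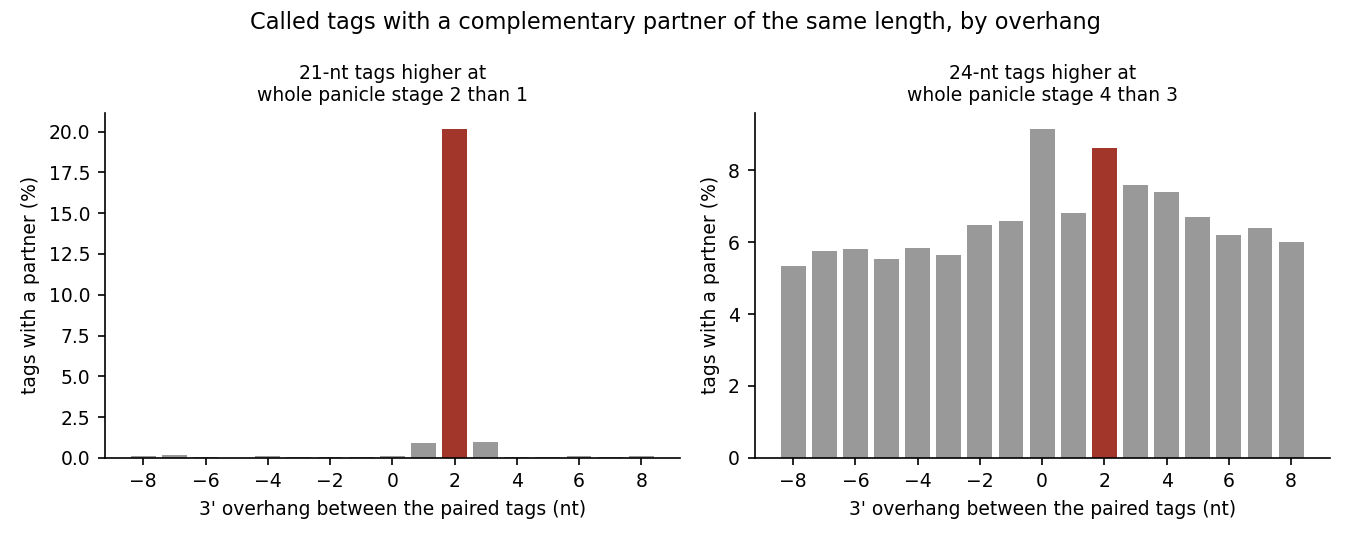
Share of risen tags (percent, y axis) that have a complementary tag in the same set at each 3' overhang (nt, x axis), for the 21-nt tags of whole panicle stage 2 against 1 and the 24-nt tags of stage 4 against 3. At an overhang of 2 nt the share was 20.1% for 21-nt tags that rose at whole panicle stage 2, and for 24-nt tags that rose at stage 4 it was 8.62%, under the 9.14% at an overhang of 0.

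From stage 2 to stage 3, as the whole panicle began to emerge, no miRNA family passed in edgeR. The trigger miR2275 had 2.09 ± 0.28 CPM at stage 3 and 0.968 ± 1.14 at stage 2 (log2 change 1.15, SE 0.74, adjusted p = 0.477), and miR2118 had 8.73 ± 0.96 and 7.50 ± 4.45 CPM (0.22). For miR390 the change was -0.72 (29.8 against 49.2 CPM) and for tasiR-ARF -0.30 (5.50 against 6.80 CPM). None of the 9 lists held a family past the threshold, over all families or adjusted over the list alone. Unadjusted, 2 families were under 0.05, DESeq2 called 1, and without stage 2 replicate 1 edgeR called 3, with miR2275 at 3.66. The median change of families was -0.30, and from -0.34 to 0.01 over the other scalings.

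Few single tags passed between stages 2 and 3. At 21 nt 35 rose and 0 fell with 1819 at an unadjusted p under 0.05, and 30 of the 35 were carried by stage 3 replicate 2, without which 0 passed. Leaving out stage 2 replicate 1 gave 314, stage 2 replicate 2 gave 20 and stage 3 replicate 1 gave 212. At 24 nt 1 tag rose, named after its values were seen, with 22 and 91 reads at stage 3 and 1 and 0 at stage 2, and 8 fell with both stages apart. The 24-nt count of 9 became 876 with DESeq2 (854 up), and 5029, 170, 205 and 187 without replicates 1 and 2 of stage 2 and 1 and 2 of stage 3. The median change was 0.52 at 21 nt and 0.10 at 24 nt, and with DESeq2 0.41 and 0.17. TMM factors gave 0 up and 8 down at 24 nt.

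From stage 3 to stage 4, at full emergence, 24-nt tags rose while no family passed over all 29. Of the 24-nt tags 13569 rose and 609 fell. The risen set summed to 354 CPM at stage 1, 1864 at stage 2, 5071 ± 666 at stage 3, 38950 ± 18941 at stage 4 and 65865 ± 8596 at stage 5, and to 4931, 17074 and 32457 ± 6119 CPM in spikelet stages 2, 3 and 4, with 343 CPM in leaf. The starter of 24-nt phasiRNA production in grass anthers, miR2275, had 2.65 ± 0.44 CPM at stage 4 and 2.09 ± 0.28 at stage 3 (log2 change 0.34, not past the threshold). In 13489 of the 13569 tags both stage 4 libraries exceeded both stage 3 libraries, and 176 were carried by 1 library. The stage 4 replicates correlated across 24-nt tags with an r of 0.799, against 0.914 for those of stage 3. The 24-nt calls, 14178 in both directions, numbered 3440 without stage 3 replicate 1, 7446 without stage 3 replicate 2 and 3392 without stage 4 replicate 2. The median change over 24-nt tags was 0.01 and from 0.00 to 0.13 over the other scalings.

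**Figure D4:**
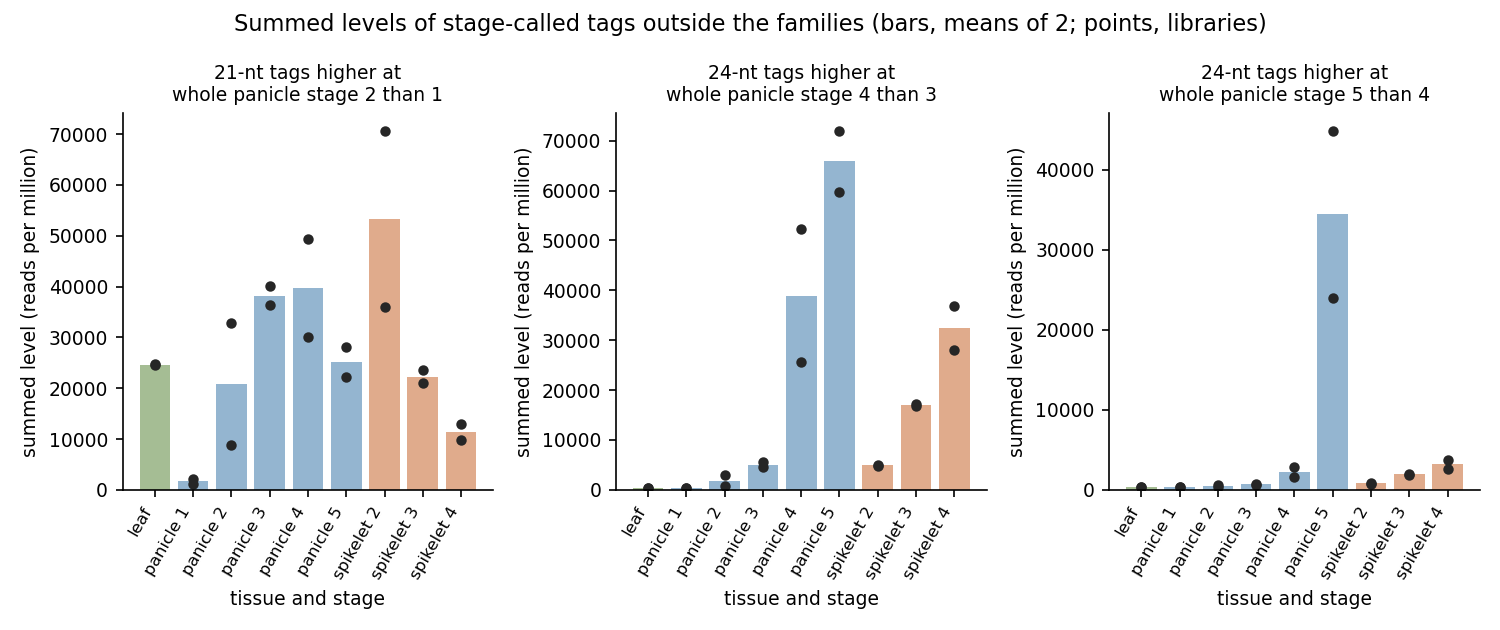
Summed levels (CPM, y axis) of 3 sets of risen tags outside the miRNA families in the 9 groups (x axis), with points for libraries and bars for means of 2. The 21-nt set risen at whole panicle stage 2 went from 1644 CPM at stage 1 to 38180 at stage 3, and the 24-nt set risen at stage 4 from 5071 CPM at stage 3 to 65865 at stage 5.

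At 21 nt 40 tags rose from stage 3 to stage 4 and 15 fell, and 13 of the 15 were carried by stage 3 replicate 1. The sum of 55 was 1 without that library, 114 without stage 3 replicate 2, 100 and 27 without stage 4 replicates 1 and 2, and it was 188 with DESeq2 (177 up, 11 down) and 102 with TMM factors (87 up, 15 down). The median change was -0.06, with DESeq2 0.23. No family passed over all 29 in edgeR, with 7 at an unadjusted p under 0.05, 5 called by DESeq2, 5 by TMM factors and 3 without stage 4 replicate 1. Adjusted over the list alone, 2 families passed in auxin response, miR167 (log2 change 1.32, SE 0.45) and miR393 (1.42), and 1 each in anther and GAMYB (miR159, 0.95), nutrient and copper response (miR399, 1.86) and other conserved (miR169, 1.76), all named after their values were seen, each with an adjusted p of 0.0728 over all families. The remaining lists held 0. Changes of miR2118 (-0.22), miR390 (-0.42) and tasiR-ARF (-0.86, adjusted p = 0.231) did not pass. The median over families was 0.33, and from -0.05 to 0.43 over the other scalings.

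From stage 4 to stage 5, after pollination, a further set of 24-nt tags rose, 10594 in number, and 7804 fell. The risen set summed to 2227 CPM at stage 4, 34431 ± 14753 at stage 5, 3185 in spikelet stage 4 and 406 in leaf. At 21 nt 1035 tags rose and 107 fell. The risen ones had a median log2 change of 8.01 and a GC content of 60.8%, and 16.9% had a partner at the 2-nt overhang, against 4.64% to 10.2% at the other overhangs. Groups were apart for 10582 of the risen 24-nt tags and 1034 of the risen 21-nt tags. The median change was -0.62 at 24 nt and -0.53 at 21 nt, and TMM factors moved it to 0.17 and 0.26 and DESeq2 to 0.25 and -0.42, so that risen and fallen 24-nt tags numbered 17268 and 1083 or 10936 and 444. DESeq2 called 100 tags at 21 nt. The 24-nt count of 18398 fell to 11006 without stage 4 replicate 1 and to 3373 and 10834 without stage 5 replicates 1 and 2, and the 21-nt count of 1142 to 685 without stage 4 replicate 1 and 319 without stage 5 replicate 1.

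No family passed from stage 4 to stage 5 in edgeR, with 6 at an unadjusted p under 0.05, 4 called by DESeq2 (2 up, 2 down), 11 by TMM factors, all up, and 1 without stage 4 replicate 2. Adjusted over the list alone, both families of silencing machinery passed, miR168 (log2 change -1.16, SE 0.35, adjusted p over all families 0.0501) and miR162 (-1.03, SE 0.41, 0.145), with 1 each in nutrient and copper response (miR397, a regulator of laccase genes, 1.68, SE 0.48, 0.0501) and anther and GAMYB (miR159, a regulator of GAMYB genes, 0.77, SE 0.35, 0.214), named after their values were seen, and 0 in the other lists. The triggers had changes of -0.50 (miR2118, adjusted p = 0.514), -0.42 (miR2275) and -0.57 (miR390), and tasiR-ARF -0.62, none past the threshold and each positive with TMM factors (0.31, 0.39, 0.23 and 0.18). The median over families was -0.07, and from -0.19 to 0.74 over the other scalings.

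**Figure D5:**
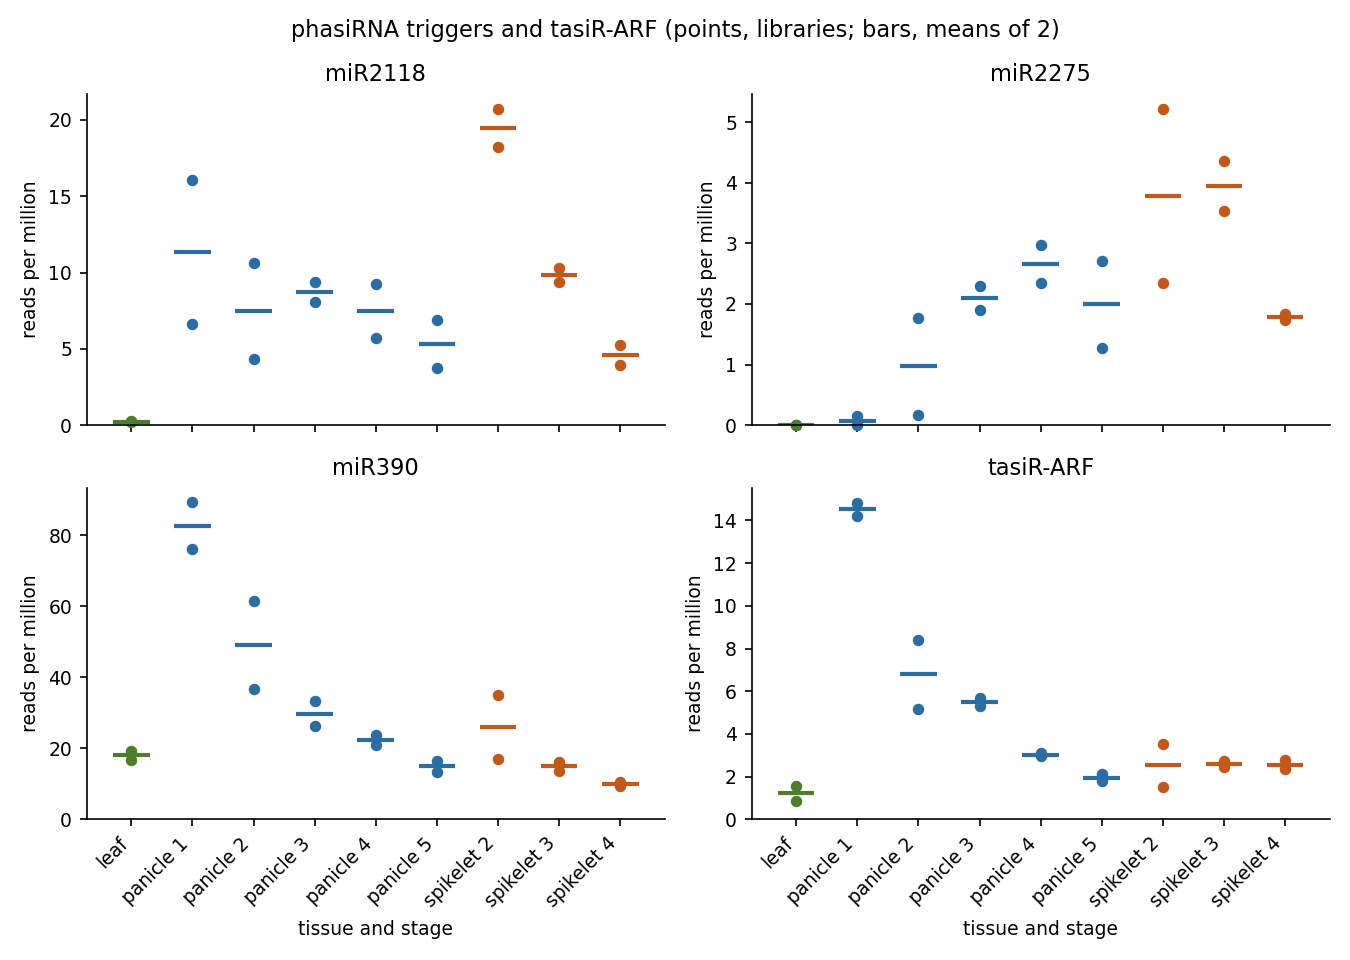
Levels (CPM, y axis) of miR2118, miR2275, miR390 and tasiR-ARF in the 9 groups (x axis), with points for libraries and lines at means of 2. Mean miR390 was 82.8 CPM at whole panicle stage 1 and 14.9 at stage 5, and mean miR2118 was 0.217 CPM in leaf and 19.5 in spikelet stage 2.

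Across all whole panicle stages, each family's most abundant sequence and group means give the course of the phasiRNA triggers. The most abundant miR2118 sequence was TTCCCGATGCCTCCCATTCCTA (24.2% of its family's reads), and the family had 11.3 ± 6.68, 7.50 ± 4.45, 8.73 ± 0.96, 7.50 ± 2.49 and 5.31 ± 2.23 CPM at stages 1 to 5. That of miR2275 was TTCAGTTTCCTCTAATATCTCA (33.3%), with 0.0717, 0.968, 2.09, 2.65 and 1.99 CPM. For miR390, AAGCTCAGGAGGGATAGCGCC (88.4%), the means were 82.8 ± 9.39, 49.2 ± 17.4, 29.8 ± 5.06, 22.3 ± 2.00 and 14.9 ± 2.18 CPM, and for tasiR-ARF 14.5 ± 0.44, 6.80 ± 2.28, 5.50 ± 0.30, 3.02 ± 0.086 and 1.96 ± 0.21. The course of tasiR-ARF depended on the matching: exact matches numbered 14 and 25 reads in the libraries of stage 1, 57 and 30 at stage 2, 50 and 47 at stage 3, 33 and 27 at stage 4 and 27 and 14 at stage 5. No single contrast between adjacent stages passed for miR390 or tasiR-ARF over all families, and stage 5 was not tested against stage 1.

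In spikelets from stage 2 to stage 3, 8 of 29 families rose and 1 fell. Levels of miR167 rose by 1.85 on the log2 scale (SE 0.46, 606 against 168 CPM, adjusted p = 0.00830) and those of miR393 by 2.02 (SE 0.50, 6.37 against 1.50 CPM, adjusted p = 0.00830). The growth regulator miR396 rose by 1.77 (SE 0.47, 26639 against 7835 CPM, adjusted p = 0.00849), as did miR171, which acts on GRAS genes, by 1.77 (SE 0.47). The phosphate-response miRNA miR399 rose by 2.07 (SE 0.60), miR172, a repressor of floral identity genes of the APETALA type, by 1.96 (SE 0.61, 0.668 against 0.15 CPM, from 6 and 1 reads at stage 2), miR159 by 1.09 (SE 0.35) and miR444, which acts on MADS-box genes, by 0.95 (SE 0.32), and miR408, a copper-response miRNA, fell by 1.29 (SE 0.46, 4.56 against 11.2 CPM, adjusted p = 0.0353). The triggers did not pass, with miR2118 at -0.99 (SE 0.48, 9.81 against 19.5 CPM, adjusted p = 0.113), miR2275 at 0.04, miR390 at -0.79 (adjusted p = 0.112) and tasiR-ARF at -0.01. For the 9 called families both libraries of the higher group lay above both of the lower.

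By list, phase change and inflorescence, auxin response and meristem and organ patterning each had 2 families up, of 5, 3 and 5, anther and GAMYB 1 up of 1, and nutrient and copper response 1 up and 1 down of 7. The rest had 0, and adjusted over the list alone the numbers were the same except 3 in nutrient and copper response, with miR528 at -1.87 named after its values were seen. None of the 9 calls was kept without stage 2 replicate 2, or without stage 3 replicate 1, 5 were made without stage 3 replicate 2, and without stage 2 replicate 2 miR396 had 1.12 and miR408 -0.62, while miR167 had 1.67, miR159 0.95, miR399 2.49 and miR444 1.10. The change of miR172 was 3.10 and 1.54 without stage 2 replicates 1 and 2, and it did not pass in the latter case or with DESeq2. With exact matches miR399 had 1.76 and did not pass. The families' median change was 0.50, and from 0.02 to 0.69 over the other scalings, with 9 up and 0 down under TMM factors, 5 and 7 under DESeq2 and 6 and 2 without the oligo in library size.

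Single tags in spikelet moved both ways from stage 2 to stage 3. At 21 nt 700 rose and 4622 fell, the fallen ones summing to 30736 CPM at stage 2 and 2985 at stage 3. At 24 nt 2217 rose, of which 79.5% started with A at a GC content of 44.6%, and 2506 fell, of which 58.9% started with C at 55.6%. Tags not called started with A in 51.0% and with C in 19.9%. Among distinct 24-nt sequences, stage 2 replicate 2 had 31.1% A and 32.3% C, against 49.1% and 18.7% in replicate 1. The first bases of the called tags may thus follow that library rather than the stage. Groups were apart for 4512 of the fallen 21-nt tags, and 503 were carried by stage 2 replicate 2. The 21-nt count of 5322 was 1040 without that library, 13581 without stage 2 replicate 1, 1759 and 1525 without stage 3 replicates 1 and 2, and 8548 with DESeq2. The 24-nt count of 4723 was 1517, 29696, 2493 and 2613 without the same libraries, and 8268 with DESeq2 (4965 up, 3303 down), with 2750 up and 1888 down under TMM factors and 1564 and 3208 without the oligo in library size. The median change was -0.26 at 21 nt, and from -1.03 to -0.13 over the other scalings.

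From stage 3 to stage 4 in spikelet, miR529 fell by 2.30 (SE 0.45, 142 against 698 CPM, adjusted p = 0.00129) and miR159, the GAMYB regulator, by 1.60 (SE 0.35, 1305 against 3945 CPM, adjusted p = 0.00273). The phosphate-response miRNA miR827 fell by 1.64 (SE 0.54, 0.903 against 2.83 CPM, adjusted p = 0.0475). The sulfate-response miRNA miR395 had 51 reads at stage 3 and 0 at stage 4, at least 13.9-fold lower (adjusted p = 0.0475), and 46 of the 51 were in replicate 1. With exact matches miR395 had 0 and 2 reads in the libraries of stage 3, too few for a comparison. The triggers miR2118 (-1.09, adjusted p = 0.219), miR2275 (-1.14, adjusted p = 0.372) and miR390 (-0.57) and tasiR-ARF (-0.02) did not pass. By list 1 family was down of 5 in phase change and inflorescence, 1 of 1 in anther and GAMYB and 2 of 7 in nutrient and copper response, and 0 in the others, with the same numbers adjusted over the list alone. In all 4 both stage 4 libraries lay below both stage 3 libraries.

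Of these calls miR395 and miR827 were not made with TMM factors, and 2, 1 and 2 families passed without stage 3 replicate 1 and stage 4 replicates 1 and 2. The median change of families was -0.32, and from -0.26 to 0.14 over the other scalings, with 1 up and 4 down under DESeq2 and 2 up and 2 down with library size from miRNA reads. At 24 nt 265 tags rose and 417 fell, all with the groups apart, and 84.2% of the fallen started with A and 55.8% of the risen with C. Tags not called started with A in 50.6% and with C in 20.4%. Among all distinct 24-nt sequences A went from 53.0% at stage 3 to 43.5% at stage 4 and C from 15.9% to 24.7%. The first bases of the called tags may thus follow the composition of whole libraries. DESeq2 called 5521 up and 1185 down, TMM factors 1203 and 307, and library size from 20 to 24 nt reads 450 and 295, and the 682 calls became 1843 without stage 3 replicate 1 and 1420 without stage 4 replicate 1. At 21 nt 0 rose and 5 fell in edgeR, with 3226 at an unadjusted p under 0.05, and DESeq2 called 36 up and 38 down. Of these 5, looked at after their values were seen, 4 were carried by stage 3 replicate 1 (232, 331, 533 and 1395 reads against 1 in replicate 2) and 1 had 140 and 359 reads against 6 and 4. The count was 47 without stage 3 replicate 2 and 8 without stage 4 replicate 1, and the median change was -0.46 at 21 nt and -0.11 at 24 nt, and from -0.40 to -0.13 and from -0.07 to 0.19 over the other scalings.

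Spikelet was compared with whole panicle at the same stages to separate the flower-bearing units from the branches that the whole panicle also holds. The largest change was that of miR172, lower in spikelet by -3.36 (SE 0.29, 0.479 against 4.63 CPM, n = 6 each, adjusted p = 4.5e-09), with all 6 spikelet libraries below all 6 whole panicle libraries. The silencing regulator miR168 was 2.30-fold lower (log2 SE 0.20, 854 against 2080 CPM, adjusted p = 1.0e-04), and miR162 fell by 1.15 (SE 0.24, 151 against 330 CPM). Levels of miR390 fell by 1.02 (SE 0.22, 17.0 against 33.8 CPM, adjusted p = 8.7e-04) and of tasiR-ARF by 0.91 (SE 0.26, 2.56 against 5.11 CPM, adjusted p = 0.00571), the latter at -0.26 and not past the threshold with exact matches. The growth regulator miR396 fell by 1.08 (SE 0.27, 20419 against 38019 CPM), miR164 by 1.75, miR397 by 1.31, miR399 by 1.28, miR827 by 1.14 and miR535 by 1.01. The triggers miR2118 (0.28, SE 0.28, 11.3 against 7.91 CPM) and miR2275 (0.79, SE 0.41, 3.17 against 1.90 CPM) did not pass.

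By list 5 of 5 families were lower in phase change and inflorescence, 1 of 3 in phasiRNA triggers, 1 of 1 in TAS3 product, 1 of 3 in auxin response, 3 of 5 in meristem and organ patterning, 3 of 7 in nutrient and copper response, 2 of 2 in silencing machinery and 0 in the others, the same numbers as adjusted over the list alone. These 16 calls, all lower, depend on the scaling: the median change of families was -0.77 and from -0.70 to 0.01 over the other scalings, and the numbers up and down were 5 and 8 with TMM factors, 9 and 2 with DESeq2, 3 and 16 with library size from miRNA reads and 3 and 13 with that from 20 to 24 nt reads. Reads under 20 nt and 5.8S rRNA fragments also had higher means in spikelet than in whole panicle at stages 3 and 4, and lower means at stage 2. Only miR172 and miR168 were called lower under every scaling, miR529 and miR160, named after their values were seen, turned to 0.01 and 0.08 with DESeq2, and miR2275 passed as higher in 4 of the other scalings (0.94 to 1.67) and miR2118 with TMM factors (0.75) and DESeq2 (1.10).

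Averaged over stages 2, 3 and 4, single tags were mostly lower in spikelet. Within stage 2, however, the median log2 difference of 21-nt tags was 0.510, against -0.461 and -1.11 within stages 3 and 4. At 21 nt 758 rose and 5699 fell, and at 24 nt 6127 rose and 33034 fell. Of the risen 24-nt tags 69.9% started with A, against 31.8% of the fallen. The median change was -0.49 at 21 nt and -0.56 at 24 nt, and over the other scalings it ran from -0.41 to -0.04 and from -0.49 to 0.08. At 24 nt the numbers up and down were 10545 and 11644 with TMM factors, 15807 and 5462 with DESeq2 and 8486 and 19919 with library size from 20 to 24 nt reads, and at 21 nt 2021 and 3054, 1412 and 2229, and 1248 and 3846. The 21-nt count of 6457 was 10738 without spikelet stage 2 replicate 2 and 4117 without whole panicle stage 4 replicate 1, and with both stage 2 groups left out it was 13107.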

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

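The tests of the kit oligo and reads related to it, of other 22-nt RNA, of sampling points on the axis from stage 1 to stage 3 and of the other splits of the samples were chosen after the results they concern had been seen, as was the spread of medians between stages.

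The change from stage 3 to stage 4 differed between spikelet and whole panicle for 2 miRNA families in edgeR, by a test of the interaction. For miR529, a regulator of SPL genes, the difference was -2.79 on the log2 scale (SE 0.62, adjusted p = 0.00270), with 698 ± 73.0 and 142 ± 10.5 CPM in spikelet and 585 ± 5.75 and 821 ± 55.8 in whole panicle. For miR159, a regulator of GAMYB genes, it was -2.55 (SE 0.50, adjusted p = 0.00125), with 3945 ± 28.5 and 1305 ± 65.5 CPM in spikelet and 1311 ± 181 and 2533 ± 1040 in whole panicle. Both directions held under each scaling, and with library size from miRNA reads miR529 no longer passed at -1.91. From stage 2 to stage 3 the interaction called 0 families in edgeR, with 10 at an unadjusted p under 0.05, 3 by DESeq2 and 6 with TMM factors.

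Among 21-nt tags the change from stage 2 to stage 3 differed between the tissues for 5175 tags, 135 more positive in spikelet and 5040 more negative. In 4361 of them spikelet stage 2 replicate 2 had the highest level, 657 had their highest library at least 10-fold above its replicate, and with spikelet stage 2 replicate 2 left out 2227 tags passed. At 24 nt 462 tags passed, 27 more positive and 435 more negative, with spikelet stage 2 replicate 2 the highest in 405. From stage 3 to stage 4 the interaction called 2 tags at 21 nt and 21 at 24 nt, with 2150 and 17772 at an unadjusted p under 0.05, and the 24-nt count was 1076 with DESeq2. Both 21-nt tags, looked at after their values were seen, rested on single libraries: 1 had 62 and 0 reads in whole panicle stage 4 and 232 and 1 in spikelet stage 3, the other 70 and 4 and 44 and 1. Of the 21 tags at 24 nt 3 had their highest library at least 10-fold above its replicate.

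The share of 22-nt reads was 25.9% in leaf and 14.8% in panicle and spikelet. With the kit oligo removed from reads and totals the shares were 8.29% and 6.89%, and 12.6% of the difference was left, which argues against other abundant 22-nt RNA of leaf as the main source. What was left was 2.44 SD of the panicle and spikelet libraries (SD 0.574 percentage points), so reads of the exact oligo were not the whole cause. With oligo fragments and reads that share a run of 15 bases with the oligo or have up to 3 mismatches to it also removed, the shares were 7.46% and 6.51%, 1.14 SD apart (SD 0.837). The difference fell from 1.40 to 0.954 points, and the rest of the fall in SD units came from the larger SD. Oligo reads with errors or shifted ends thus accounted for a part of what was left, and most of it remained. A smaller difference in 22-nt RNA between tissues stays open, with n = 2 for leaf.

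Over 21-nt tags, replicates of whole panicle stage 2 and of spikelet stage 2 resembled each other less than those of the other 7 groups. Over 24-nt tags the whole panicle stage 4 pair (r = 0.799) was also below the whole panicle stage 2 pair (r = 0.821). At an equal depth of 9725946 reads without the oligo their r over 21-nt tags were 0.766 and 0.650, and the median of the other pairs stayed 0.125 above the higher of these, which argues against depth and the oligo reads themselves, though the gaps in oligo share of the 2 pairs (3.22 and 22.4 percentage points) were the largest. The gap in reads under 20 nt ranked with dissimilarity over the 9 pairs with a Spearman rho of 0.65 (permutation p = 0.0649, two-sided) and a Pearson r of 0.395 (permutation p = 0.280, and r of 0.157 without the 2 pairs farthest from the median), and the gaps in 5.8S rRNA were largest in the same 2 pairs (0.374 and 0.651 points), so RNA degradation and sample differences cannot be told apart with 9 pairs. On an axis over 6831 rising 21-nt tags chosen from whole panicle stages 1 and 3 alone, from 0 at stage 1 to 1 at stage 3, stage 2 replicates 1 and 2 lay at 0.87 and 0.35, which is 0.52 apart, spikelet stage 2 replicates at 0.792 and 1.26, and whole panicle stage 4 replicates, which do not stand apart by r over 21-nt tags, at 1.09 and 0.781. Over the 148 falling tags the whole panicle stage 2 replicates lay at 0.885 and 0.408 and the spikelet stage 2 replicates at 0.419 and 1.49. Leaf lay at 0.955 and 0.947 on the falling tags, so that axis does not follow stage alone. Panicles collected at different points between these stages may contribute to the whole panicle pair, but such gaps were not particular to it, and no biological explanation was tested for the spikelet pair.

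Averaged over stages 2, 3 and 4, most families and tags were lower in spikelet than in whole panicle. Of 100 splits drawn from 108 possible splits within stages, 1, the real one, gave as many called families (16, highest other 13) and 1 as many called 24-nt tags (1441 of 5000 sampled tags, highest other 1096). That is the smallest share that 100 splits can give, so chance is unlikely for these but not excluded. At 21 nt 4 splits, the real one included, gave as many (1106 of 5000, highest other 2248), under 0.05 of the splits, and a split with 2248 points to a structure of the samples besides tissue. Library size from 20 to 24 nt reads without the oligo moved the median change from -0.56 to -0.31 at 24 nt and from -0.49 to -0.22 at 21 nt. The 24-nt value passed the bound of -0.25, set beforehand as counting against reads outside 20 to 24 nt as the cause. With the same library size, 24-nt medians calculated within stages 2, 3 and 4 were -0.0513, -0.146 and -0.412. They fell with stage, and their mean of -0.203 (SD 0.187) did not reach the bound. Reads outside 20 to 24 nt as the cause of the lower levels therefore cannot be told apart from tissue. At 21 nt the medians within these stages were 0.646, -0.271 and -0.713, so that spikelet was higher at stage 2. The direction depends on the scaling, reads under 20 nt (6.68% and 6.04% against 4.70% and 3.53%) and 5.8S rRNA (0.905% and 1.12% against 0.712% and 0.437%) were higher in spikelet at stages 3 and 4, so RNA degradation stays open and untested here, and a higher content of other small RNA in spikelet and a lower level of most of these RNAs could both give it, which CPM alone leave open.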

How the results depend on the processing

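Leaving the kit oligo out of library size or of the shares, taking library size from 20 to 24 nt reads, leaving out the stage 2 groups and, for tags, DESeq2 and leaving out single libraries were chosen after the data had been seen. Of 434 counts of calls under alternatives, 286 stayed within 1.5 times the reported count. Of 1272 log2 changes of named families, 1133 kept direction and side of the threshold, 88 no longer passed, 20 newly passed and 31 changed sign, and of 245 differences in shares 227 were the same. Allowing 2 mismatches changed none. Leaving out the low-count filter, done for families only, could change none, since all 29 families had passed it. Planned settings for phased loci, for the share of reads in them and for their base composition were not run, since no genome was used. Except where fewer libraries or tags entered, the cause was not tested for any value below. Low counts limit miR2275, miR164 and miR395, and the spread between 2 libraries limits adjacent stages.

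With DESeq2, families called at whole panicle stages 3, 4 and 5 against the stage before numbered 1, 5 and 4 (0 each as reported), and 3 in the interaction of stage 3 against 2 (0). Its 21-nt calls were 188 at whole panicle stage 4 against 3 (55), 100 at 5 against 4 (1142), 8548 and 74 at spikelet stages 3 and 4 (5322 and 5), 3641 in spikelet against whole panicle (6457) and 69 in the interaction of 4 against 3 (2). Its 24-nt calls were 2341, 876 and 11380 at whole panicle stages 2, 3 and 5 (578, 9 and 18398), 8268 and 6706 at spikelet stages 3 and 4 (4723 and 682), 21269 in spikelet against whole panicle (39161) and 1036 and 1076 in the interactions (462 and 21). Log2 changes were -0.49 for miR2275 at spikelet stage 3 against 2 (0.04) and 0.19 for tasiR-ARF at 4 against 3 (-0.02).

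With TMM factors families numbered 5 and 11 at whole panicle stages 4 and 5, 2 at spikelet stage 4 (4) and 6 in the interaction of 3 against 2. At 21 nt the calls were 15 and 102 at whole panicle stages 3 and 4 (35 and 55) and 0 at spikelet stage 4, and at 24 nt 10 at whole panicle stage 2, 1510 at spikelet stage 4, 22189 in spikelet against whole panicle and 230 and 2 in the interactions. Changes turned to -0.0139 for miR390 in panicle against leaf, to 0.31, 0.39, 0.23 and 0.18 for miR2118, miR2275, miR390 and tasiR-ARF at whole panicle stage 5, and to 0.10 and 0.32 for tasiR-ARF at spikelet stages 3 and 4.

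With library size from 20 to 24 nt reads without the oligo, families numbered 2 at whole panicle stage 5, 2 at spikelet stage 4 and 3 in the interaction of 3 against 2. The 21-nt calls were 11 and 27 at whole panicle stages 3 and 4 and 0 at spikelet stage 4, the 24-nt calls 13 at whole panicle stage 2 and 5 in the interaction of 4 against 3, and tasiR-ARF had 0.0370 and 0.13 at spikelet stages 3 and 4. With the oligo alone left out, 2 families passed at spikelet stage 4, 21-nt calls were 16 at whole panicle stage 3 and 0 at spikelet stage 4, 24-nt calls 255 at spikelet stage 4 and 11 in the interaction of 4 against 3, miR2275 had -0.0915 at spikelet stage 3 and tasiR-ARF 0.0393 at stage 4. With library size from miRNA reads families numbered 2 at whole panicle stage 5 and 1 in each interaction (0 and 2), and tasiR-ARF had 0.0475 and 0.48 at spikelet stages 3 and 4.

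With exact matches miR2275 had no reads, families numbered 4 and 2 at whole panicle stages 4 and 5 and 1 in the interaction of 3 against 2, and tasiR-ARF had 0.88 at whole panicle stage 2 (-1.10) and 0.22 and 0.51 at spikelet stages 3 and 4. Fits of the compared groups alone, which hold fewer samples, called 4, 3 and 4 families at whole panicle stages 2, 4 and 5 (7, 0 and 0) and 5 at spikelet stage 3 (9). With at least 10 reads in 2 libraries 24-nt calls were 20 at whole panicle stage 2 and 357 at spikelet stage 4. With the stage 2 groups left out, 13107 21-nt tags passed in spikelet against whole panicle and miR2118 had -0.27 (0.28).

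In levels of families and tags, replicate numbers did not pair the libraries in most pairs of groups. Over 36 pairs, deviations of same-numbered libraries from their group means correlated over 0.1 in 10 for families, 4 for 21-nt tags and 3 for 24-nt tags (medians -0.0423, -0.00570 and -0.00735). In read lengths they did track a difference. Reads of 29 to 30 nt, which enter library size, had a higher share in replicate 1 than in replicate 2 of every group. In leaf the shares were 4.59% and 0.934%, and in spikelet stage 2 they were 3.11% and 0.472%. The kit oligo share was higher in replicate 2 of every group except whole panicle stage 2. A replicate block gave 9 calls at 21 nt at whole panicle stage 3 and 0 at spikelet stage 4. At 24 nt the block gave 13 at whole panicle stage 2, 352 at spikelet stage 4 and 220 and 4 in the interactions, and tasiR-ARF had 0.0184 at spikelet stage 3. Among named families miR827 no longer passed at spikelet stage 4 with the block, and no other call changed.

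Shares over distinct sequences changed the sign of differences. Panicle minus leaf was -0.0029 at 24 nt (10.6), whole panicle stages 3 to 5 minus 1 and 2 was 0.228, 1.35 and -1.24 at 20, 23 and 24 nt (-0.766, -0.556 and 4.10), and spikelet minus whole panicle was 0.170 and -0.135 at 21 and 22 nt (-1.46 and 4.83). Over 20 to 25 nt reads the difference was 0.0258 at 20 nt for panicle minus leaf (-0.0489) and 0.142 at 21 nt for spikelet minus whole panicle. With the oligo removed it was -0.853 at 22 nt for the later stages (1.25), and 0.146 and -0.0725 at 21 and 22 nt for spikelet.

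Each library was left out in turn, the lone library of its group being assumed to vary like the other groups. Since the low-count filter was also applied anew, the counts of called tags do not measure dependence on single libraries alone. Families called then ranged from 2 to 7 at whole panicle stage 2, 0 to 3 at stages 3 and 4, 0 to 1 at stage 5, 0 to 11 and 1 to 3 at spikelet stages 3 and 4, and 0 to 9 in the interaction of 3 against 2. The 21-nt calls ranged from 7626 to 15860 in panicle against leaf, 727 to 10423, 0 to 314, 1 to 114 and 319 to 1054 at whole panicle stages 2 to 5, 1040 to 13581 and 6 to 47 at spikelet stages 3 and 4, 4117 to 10738 in spikelet against whole panicle, and 2227 to 12370 and 3 to 30 in the interactions. The 24-nt calls ranged in the same order from 11073 to 36471, 127 to 6446, 170 to 5029, 3392 to 20684, 3373 to 17224, 1517 to 29696, 595 to 1843, 34668 to 58406 and, in the interactions, 774 to 14401 and 465 to 3278.

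Log2 changes then ranged for miR2118 from -1.38 to 0.18, -0.29 to 1.00 and -0.60 to 0.0854 at whole panicle stages 2, 3 and 4. For miR2275 they ranged from -1.06 to 0.0309 at whole panicle stage 5 and -0.40 to 0.76 at spikelet stage 3, and for tasiR-ARF from -0.61 to 0.0832 at whole panicle stage 3 and -0.46 to 0.75 and -0.13 to 0.10 at spikelet stages 3 and 4. Panicle minus leaf ranged from -0.116 to 0.0695 at 20 nt, -12.4 to -9.84 at 22 nt, 1.83 to 2.14 at 23 nt and 10.1 to 11.05 at 24 nt, and spikelet minus whole panicle from -9.37 to -7.95 at 24 nt.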

Other observations

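The tests of paired precursors and of first bases were chosen before their results were seen, and the values of other sequences and single libraries were picked out after it.

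At the 5 whole panicle stages miR172 had 10.4 ± 1.09, 6.87 ± 0.632, 4.53 ± 1.18, 2.51 ± 0.304 and 1.62 ± 0.012 CPM, and no adjacent pair of stages passed the test. In the spikelets of stages 2, 3 and 4 it had 0.15 ± 0.109, 0.668 ± 0.030 and 0.618 ± 0.0531 CPM, and leaf had 7.74 ± 0.128. A repressor of floral identity genes was thus present at higher levels in whole panicles, which also hold branches and bristles, than in the spikelets taken from the same stages, while the part of the panicle it came from was not measured.

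Spikelet stage 2 replicate 2, the library of the lowest depth and the highest oligo share (28.9%), also had another composition. Among its distinct 24-nt sequences 31.1% started with A and 32.3% with C at a GC content of 54.9%, against 49.1%, 18.7% and 50.8% in replicate 1. On 21-nt tags it lay closest to whole panicle stage 4 replicate 1 (r = 0.779) and replicate 1 to spikelet stage 3 replicate 2 (r = 0.862), across tags, which are not independent.

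Among the most abundant sequences outside the families and the kit oligo were 3 that share a 3' end. They are GCCCCGCGTCGCACGGATTCGT of 22 nt, AGCCCCGCGTCGCACGGATTCGT of 23 nt and CAGCCCCGCGTCGCACGGATTCGT of 24 nt, with means of 8516, 12433 and 6463 CPM over the groups, and their origin was not determined. Reads of 31 to 34 nt, not used in any comparison, made up 3.17% ± 0.60 of reads in leaf, 3.69% ± 0.65 in whole panicle stage 1 and between 2.51% and 2.96% in the other groups.

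The 21-nt tags that rose at whole panicle stage 2 may be products of paired precursors. The share of tags with a partner at the 2-nt 3' overhang, 20.1%, was the highest of all overhangs from -8 to 8 nt and 228 times the median of the others, and the share starting with C was 10.5 percentage points above that of the other tested 21-nt tags. Both values are what 21-nt phasiRNAs of grasses would give, and other products of perfectly paired RNA would give the first as well. The excess of C was not particular to 21 nt. Of the 24-nt tags that rose in the same contrast 25.8% started with C, against 20.4% of those not called. The share with a partner was not computed for tags that were not called. For the 24-nt tags that rose at stage 4 the share at that overhang was 1.37 times the median of the others and not the highest, which leaves paired precursors open. The share of these starting with A was -5.62 percentage points from that of the other tested 24-nt tags (45.6% against 51.2%). Since A was the most frequent first base of those others as well, this comparison cannot exclude a preference for A as in heterochromatic small RNAs, and no genome was at hand to place the tags in phased loci.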
